A study of Homo sapiens with 6 samples.

How the data were processed

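The data were one table of mature human miRNAs in 6 libraries, 3 from micro-EVs and 3 from nano-EVs of THP-1 cells. Cells were grown in RPMI medium with fetal bovine serum, per the labels' protocols, which do not say that vesicles had been removed from the serum. The labels' protocols give sequential spins of the medium at 2000, 20000 and 100000 g. RNA was extracted with MagZol, depleted of rRNA, fragmented and made into cDNA libraries with an NEBNext Ultra RNA kit, per the labels' protocols. That text describes a preparation for longer RNA, and no small RNA preparation is given in the sources used here. Bowtie and the genome build hg38 were used, per the submitters' processing notes. The counting method, the miRNA annotation and its version are not given in the sources used here.

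The deposited values are CPM by their behaviour: every column has the sum over the table that CPM require, and the authors rounded to 2 decimals. The header of the table names no unit. Within each column, low values were whole multiples of 1 step, which gave the number of reads assigned to miRNAs in that library. Of the 4157 values above 0, 99.9% lay within 0.1 reads of a whole number. The recovered reads served for depth, for detection counts and for count tests used as alternatives. The largest and smallest libraries held 5402018 and 1050625 reads. Columns were assigned to micro-EVs or nano-EVs by the letter M or N in their names, the initials used in the sample titles. The other letters are explained by no label, so libraries carry no replicate number from the labels. All 6 columns were used. The design text of the series also mentions first trimester placentae, and no source used here says what the letter P, shared by all columns, stands for. That the columns hold THP-1 vesicles rests on the sample labels, which name THP-1 cells for all 6 samples, and no sample with a placental label was analysed here.

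The planned test assumed counts, with a test on log values if the table held a normalized unit, and the latter was used. Values were tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3, with a trend in the variance, over miRNAs of at least 1 CPM in at least 3 libraries. P-values were adjusted by Benjamini and Hochberg over the 576 tested miRNAs, with a threshold of 0.05, and no covariate was used. Standard errors are those of limma, except for the let-7 medians, where they are errors of a median over members. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and, beside it, with an estimated correlation and with fry, adjusted over the lists. The p-values with an estimated correlation depend on few libraries. Fry asks whether a list's members move on balance in one direction and does not compare them with other miRNAs. Composition and detection were compared with two-sided exact permutation tests over the 6 libraries.

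A total of 20 lists were fixed before the data were examined, as were the tests and the rule for named miRNAs, and 18 lists had enough members to be tested. The lists covered the let-7, miR-15/16, miR-29, miR-30 and miR-548 families, the miR-17~92 and miR-23/24/27 clusters, myeloid, inflammation-responsive, GGAG-motif and high-numbered miRNAs, and miRNAs overlapping other abundant RNA. Others held markers of erythrocytes, platelets and liver, of lymphoid, stromal and endothelial, epithelial, muscle and neural cells, the placental chromosome 19 cluster and the imprinted 14q32 cluster. The name range written for the chromosome 19 cluster took in 11 miRNAs from other chromosomes, which were dropped, leaving 66. Named miRNAs were those past the threshold without overlap between the groups that had the 10 largest changes in each direction at a mean of at least 10 CPM, the 10 most abundant, and up to 4 of each list by abundance. MiRNAs named beyond that rule, chosen after their values were seen, were let-7b-3p, let-7b-5p, let-7d-5p, miR-320a-3p, miR-320b, miR-320c, miR-423-5p, miR-99a-5p, miR-223-3p, miR-142-3p, miR-375-3p, miR-203a-3p, miR-1260a and miR-1260b. MiR-223-5p was likewise named after its values were seen.

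MiRNAs with the same mature sequence, such as miR-199a-3p and miR-199b-3p, had identical values, and reads of a miRNA with several hairpins cannot be divided between them. There were 5 groups of identical values that reached 10 CPM or more in any library. Hairpin positions and host genes came from GENCODE release 29 on GRCh38, the same assembly as hg38, in which 2576 of the listed miRNAs had a hairpin.

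The scripts were tested on simulated counts made from the real means and depths of this comparison at a dispersion of 0.05, with 200 miRNAs changed. Both groups had that dispersion, while real nano-EV libraries varied more than micro-EV libraries (Pearson's r 0.956 to 0.970 against 0.975 to 0.980). The rates below were not obtained under such unequal spread. When the changed miRNAs each held under 1% of reads, limma tested 666 miRNAs and recovered 63% of changes of 1 and 98% of changes of 2 on the log2 scale, with 5.3% false calls. When abundant miRNAs also changed, false calls among those of limma rose to 40.2% over 680 tested miRNAs, because shares of a fixed total shift together, and edgeR with TMM scaling gave 1.7% over 406. The real libraries have such abundant changes, so values are reported as shares, and small fold changes depend on the scaling. The list test was run only where the changed miRNAs each held under 1% of reads. There it recovered the 1 changed list and called none of 19 unchanged lists. It was not tried with abundant changes, and other splits of the real libraries called up to 4 lists.

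Alternatives were other pseudocounts (0.1 and 10), other filters, leaving out each library, edgeR 4.0.16, DESeq2 1.42.0 and limma voom on the recovered reads, other scalings, and other ways to count composition and detection. TMM-scaled CPM, edgeR with TMM on the recovered reads, thinning to equal depth for miRNAs and lists (planned for detection), removal of miR-1246 and miR-1290, and the column letter as a block were added after the data were seen. The edgeR test on recovered reads with TMM scaling called 238 of 387 miRNAs. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.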

Results

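MicroRNAs were measured in extracellular vesicles (EVs) shed into culture medium by THP-1 cells, an established human leukemia line of monocytic character. Sequential centrifugation gave 2 vesicle pellets. Debris was cleared at 2000 g, the larger micro-EVs were pelleted at 20000 g, and the smaller nano-EVs were pelleted at 100000 g. Each group had 3 libraries. Libraries are called A, B and C after the first letter of their column names, a letter that the sample labels do not explain. The second letter, M or N, gave the vesicle class, and the last letter, P in every column, is unexplained. The sources used here do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

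The deposited values were CPM, reads of a miRNA scaled to a common library total, for 2656 mature human miRNAs, of which 1159 were above 0 in at least 1 library. Whole reads could be recovered from the steps between low values. Micro-EV libraries A, B and C held 1109116, 1055382 and 1050625 reads assigned to miRNAs. The nano-EV libraries were deeper and less even, with 5402018 reads in library A, 3504529 in B and 2617891 in C. The mean depth was 3.58 times higher in the nano-EV group. A miRNA listed at 0 could therefore lie at up to 2.71 to 2.86 CPM in a micro-EV library and up to 0.555 to 1.15 CPM in a nano-EV library, taking 3 reads as the limit. These limits cover counting error only. Across miRNAs, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.975 to 0.980 between micro-EV libraries, 0.956 to 0.970 between nano-EV libraries and 0.886 to 0.900 between the groups. No pair of libraries within a group matched to within sampling noise (chi-square per degree of freedom from 15 to 390), so none was a copy of another. That does not tell separate samples from repeated preparations of 1 sample.

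The series' design text states a comparison of vesicle expression profiles, and the files allow it between the vesicle classes of THP-1 cells. The miRNA content of nano-EVs differed widely from that of micro-EVs. Micro-EV libraries were led by the let-7 family, regulators of differentiation and proliferation, which held 47.3% ± 0.960 of reads (SD, n = 3) against 10.8% ± 3.21 (SD, n = 3) in nano-EVs. Nano-EV libraries were led by miR-1246, whose share was 29.6% ± 4.83 (SD, n = 3) against 3.5% ± 1.07 (SD, n = 3) in micro-EVs. MiR-1246 is on the fixed list of miRNAs overlapping other abundant RNA, so its reads may not all come from a miRNA. All 8 tested miRNAs typical of erythrocytes, platelets and liver, such as miR-486-5p and miR-122-5p, and 19 of 33 tested miRNAs of the imprinted 14q32 cluster were higher in nano-EVs. Both lists passed camera, but neither passed with an estimated correlation (adjusted p = 0.361 for each). Of 576 miRNAs tested with limma, 268 passed an adjusted p of 0.05, with 46.6% of these higher and 53.4% lower in nano-EVs.

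Among the most abundant miRNAs, let-7a-5p fell from 18.3% ± 0.551 of reads in micro-EVs to 4.03% ± 1.15 in nano-EVs (SD, n = 3 per group), a log2 fold change of -2.23 ± 0.24 (SE) with an adjusted p of 8.11e-05. Likewise, let-7f-5p fell from 16.6% ± 0.470 to 2.65% ± 0.970 (log2 fold change -2.72 ± 0.28). Decreases were also found for miR-30c-5p, from 7.25% ± 0.883 to 1.22% ± 0.0518, and for miR-26a-5p, from 5.38% ± 0.0938 to 2.16% ± 0.158. The share of let-7i-5p fell from 6.45% ± 0.218 to 1.70% ± 0.785. In the other direction, miR-148a-3p rose from 4.05% ± 0.177 to 12.6% ± 2.20 (log2 fold change 1.62 ± 0.19, adjusted p = 1.33e-04). MiR-92a-3p, the most abundant product of the miR-17~92 cluster, rose from 2.61% ± 0.0987 to 7.21% ± 0.171. MiR-128-3p, a miRNA abundant in brain, rose from 0.930% ± 0.115 to 4.40% ± 0.775. MiR-1246 rose by 3.12 ± 0.27 on the log2 scale (adjusted p = 2.37e-05), and miR-1290 rose from 5560 ± 1760 to 58039 ± 9000 CPM.

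The largest increases among miRNAs averaging at least 10 CPM were those of miR-543 (log2 fold change 3.67 ± 0.20), miR-6529-3p (3.66 ± 0.44), miR-1908-5p (3.58 ± 0.47), miR-1290 (3.43 ± 0.26) and miR-486-5p (3.40 ± 0.16). Next came miR-1246, miR-22-3p (2.98 ± 0.14), let-7d-3p (2.93 ± 0.20), miR-124-3p (2.83 ± 0.48) and miR-3173-5p (2.73 ± 0.42). Values and order of the low miRNAs depended on the setting: over the alternatives miR-6529-3p ranged from 1.90 to 4.31 and miR-3173-5p from 1.37 to 3.30, both keeping their calls in all 23. MiR-22-3p, known for roles in hematopoiesis, went from 236 ± 6.39 to 1881 ± 250 CPM. The largest decrease was that of miR-7704, from 998 ± 101 to 14.7 ± 3.01 CPM (log2 fold change -6.00 ± 0.19, adjusted p = 1.21e-07). It is on the fixed list of miRNAs overlapping other abundant RNA, so its reads may not all come from a miRNA. The other 9 largest decreases were those of miR-4508 (-4.96), miR-10400-5p (-4.89), miR-4492 (-4.49), miR-4497 (-4.38), miR-3960 (-4.36), miR-4488 (-4.21), miR-664a-3p (-3.91), miR-3195 (-3.82) and miR-4301 (-3.80). MiR-4488 was the most abundant of these 9 in micro-EVs, at 990 ± 119 CPM against 54.4 ± 18.8 CPM in nano-EVs. MiR-3195 ranged from -4.92 to -1.63 over the alternatives, and miR-664a-3p from -5.63 to -1.96. The latter, also on the list overlapping other abundant RNA, lay at 0, 1.43 and 5.73 CPM in nano-EV libraries A, B and C. Its limma SE was 0.64, so the size of its decrease is uncertain. Hairpins of miR-3195, miR-3960, miR-4497, miR-4488, miR-4508, miR-4492 and miR-7704 were rich in GC, from 74.6% to 92.9%. The median was 48.8% over the called lower miRNAs. MiR-4301 had 56.1% and miR-664a-3p 31.7%, and miR-1908-5p, which rose, had 80.0%. Whether GC content played a part in these decreases was not tested. Fold changes are on the log2(CPM + 1) scale, which understates the change of low miRNAs.

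Genomic positions are given on GRCh38 (hg38). The miR-1246 hairpin lies on chromosome 2 at 176600980 to 176601052, on the minus strand between annotated genes. The miR-1290 hairpin lies on chromosome 1 at 18897071 to 18897148, in an intron of ALDH4A1. Both miR-1246 and miR-1290 are on the list overlapping other abundant RNA, and whether their reads came from these hairpins was not tested. MiR-486-5p has 2 hairpins on opposite strands in the same ANK1 intron, on chromosome 8 at 41660441 to 41660508 and at 41660444 to 41660507. The miR-543 hairpin is on chromosome 14 at 101031987 to 101032064, in an intron of the long noncoding RNA MEG8. MiR-148a-3p comes from an intergenic hairpin on chromosome 7 at 25949919 to 25949986. The hairpin of miR-22-3p, on chromosome 17 at 1713903 to 1713987, is exonic in its host transcript MIR22HG, and that of miR-122-5p, on chromosome 18 at 58451074 to 58451158, is exonic in MIR122HG. The miR-7704 hairpin, on chromosome 2 at 176188843 to 176188901, overlaps an exon of HOXD1 on the same strand and an exon of HAGLR on the opposite strand. As miR-7704 is also on the list overlapping other abundant RNA, its reads may have another source, which was not tested. MiR-4488 lies on chromosome 11 at 61508596 to 61508657, outside annotated host genes. Let-7f-5p can come from 2 hairpins, on chromosome 9 at 94176347 to 94176433 and in an intron of HUWE1 on chromosome X at 53557192 to 53557274, and its reads cannot be divided between them.

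**Figure D1:**
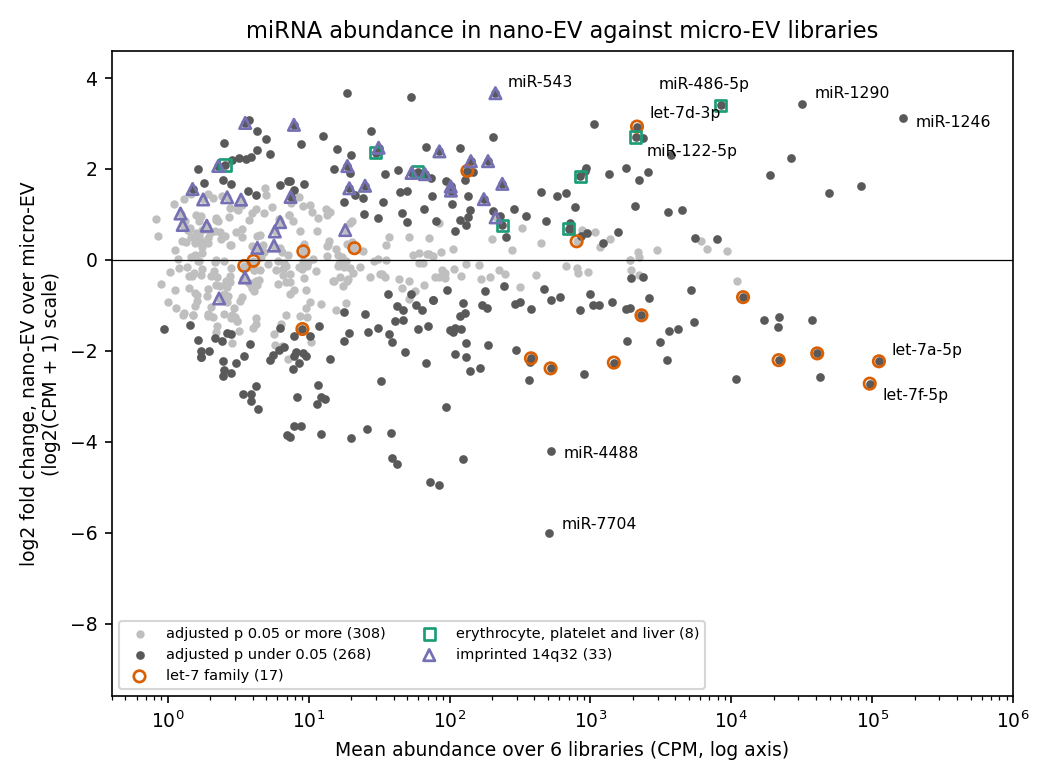
Log2 fold change of nano-EV over micro-EV libraries (vertical axis, log2(CPM + 1) scale) against mean CPM over the 6 libraries (horizontal axis, log scale) for the 576 tested miRNAs. Dark points are the 268 miRNAs with an adjusted p under 0.05, and open symbols mark the let-7 family, the erythrocyte, platelet and liver list and the imprinted 14q32 list. All 8 tested members of the erythrocyte, platelet and liver list lie above 0, while let-7a-5p and let-7f-5p lie at -2.23 and -2.72.

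Lists of related miRNAs were compared next, and 4 of 18 passed an adjusted p of 0.05 with camera at a preset correlation of 0.01. With an estimated correlation none passed after adjustment, and 1 list, the 14q32 cluster, had an unadjusted p under 0.05. Counts of members are given over all miRNAs tested. Adjusted over the list alone they were the same, except that 20 members of the 14q32 list and 7 of the myeloid list were higher and no miR-548 member passed.

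The erythrocyte, platelet and liver list rose as a whole. All 8 tested members were higher in nano-EVs, with a median log2 fold change of 2.01 (camera adjusted p = 2.55e-04; adjusted p = 0.361 with an estimated correlation). MiR-486-5p went from 1454 ± 178 to 15399 ± 2066 CPM, miR-122-5p from 535 ± 11.4 to 3659 ± 1302 CPM and miR-451a from 369.1 ± 44.5 to 1328 ± 218.9 CPM (SD, n = 3 per group). MiR-192-5p rose less, by 0.69 ± 0.16 on the log2 scale. The list's share of reads was 0.310% ± 0.0240 in micro-EVs and 2.17% ± 0.272 in nano-EVs.

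Of 33 tested members of the imprinted 14q32 cluster, 19 rose, none fell and 14 did not pass (median 1.52, camera adjusted p = 3.00e-06, adjusted p = 0.361 with an estimated correlation). MiR-543, miR-127-3p (1.67 ± 0.16) and miR-409-3p (2.17 ± 0.19) were among those that rose. MiR-379-5p, at 131 ± 15.3 CPM in micro-EVs and 294 ± 167 CPM in nano-EVs, did not pass (adjusted p = 0.122). Together the cluster held 0.0743% ± 0.00507 of micro-EV reads and 0.277% ± 0.0472 of nano-EV reads.

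The miR-30 family had 7 members that fell and 4 that did not pass out of 11 (median -1.33, camera adjusted p = 0.00598, adjusted p = 0.361 with an estimated correlation). MiR-30c-5p (-2.57 ± 0.16) and miR-30e-3p (-2.19 ± 0.12) fell, whereas miR-30d-5p, at 12423 ± 451.5 and 9379 ± 3413 CPM, did not pass. MiR-30e-5p ranged from 6063 to 20630 CPM between nano-EV libraries, with library B the highest, and its call (adjusted p = 0.0263) was lost in 9 of 23 alternative settings, among them each library left out except nano-EV library B (adjusted p from 0.0528 to 0.152). Of 18 tested miRNAs of the miR-17~92 cluster and its paralogs, a group that promotes proliferation, 11 fell, 1 rose and 6 did not pass (median -0.78, camera adjusted p = 0.0351, adjusted p = 0.457 with an estimated correlation). MiR-17-5p (-1.08 ± 0.15) and miR-20a-5p (-0.66 ± 0.15) fell, although the group's share of reads went from 4.07% ± 0.0645 to 8.20% ± 0.164 because of miR-92a-3p. The list call was lost without micro-EV library B (adjusted p = 0.0708), without nano-EV library B (0.0534), at a mean of at least 10 CPM (0.0686) and with TMM scaling (0.0615). Without miR-1246 and miR-1290 the list's median was -0.22 (adjusted p = 0.160).

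The let-7 family as a list missed the threshold (camera adjusted p = 0.0979), although it passed without nano-EV library C (0.0249), with 10 members lower, 2 higher and 5 not passing among 17 tested (median -1.22). The 10 that fell included let-7g-5p (-2.21 ± 0.30) and let-7d-5p (-2.26 ± 0.15). Those that rose were let-7d-3p and let-7b-3p (1.96 ± 0.19), the opposite hairpin arms of members that fell. Among myeloid and monocyte miRNAs, 6 were higher, 7 lower and 9 did not pass out of 22 (camera adjusted p = 0.970). MiR-223-3p, a marker of the myeloid lineage, fell by 2.64 and miR-142-3p, common to blood cells, fell by 2.51, while miR-125a-5p rose by 2.31 on the log2 scale. The more abundant arms of the first 2 hairpins moved less. MiR-142-5p, at a mean of 2594 CPM against 901 for its 3p arm, fell by 0.84. MiR-223-5p, at 1379 against 366 CPM, did not pass (0.47, limma adjusted p = 0.0756). For this list the median (0.21) and the mean (-0.08) differed in sign, with camera pointing up and fry pointing down, and the median was 0.05 without micro-EV library A and 0.33 without micro-EV library B. The inflammation-responsive list had 3 members higher, 5 lower and 11 not passing among 19 (camera adjusted p = 0.792), with a median of 0.06, a mean of -0.20 and both tests pointing down. MiR-155-5p and miR-21-5p, both induced in activated myeloid cells, fell (-1.37 ± 0.13 and -1.47 ± 0.15), and miR-221-3p rose by 0.48 ± 0.14. The call of miR-221-3p was lost without micro-EV library B (adjusted p = 0.0667), micro-EV library C (0.0935) or nano-EV library B (0.0512).

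MiRNAs whose sequence overlaps other abundant RNA took 4.19% ± 1.24 of reads in micro-EVs and 35.4% ± 5.64 in nano-EVs, most of it miR-1246 and miR-1290. Members of this list went both ways, with 4 higher, 7 lower and 9 not passing among 20 (median -0.90, camera adjusted p = 0.291). The 7 lower included miR-7704, miR-1260a (-3.01) and miR-1260b (-3.05), and miR-664a-5p rose by 0.88 while miR-664a-3p fell. Epithelial miRNAs held 0.472% ± 0.0264 of micro-EV and 0.173% ± 0.0147 of nano-EV reads, with 5 lower, 2 higher and 6 not passing among 13 (camera adjusted p = 0.291). MiR-182-5p (-1.78 ± 0.13) and miR-96-5p (-2.44 ± 0.34) fell, and miR-375-3p and miR-203a-3p rose by 2.26 and 2.41.

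The remaining lists did not pass camera. High-numbered miRNAs (number 3000 or more) had 28 lower, 12 higher and 83 not passing among 123 (adjusted p = 0.291), with miR-4488 and miR-7704 the most abundant that fell. The miR-548 family had 6 lower and 27 not passing among 33 (adjusted p = 0.291), and miR-548ad-5p and miR-548ae-5p, which carried identical values, lost their calls in 14 of 23 alternative settings, including each library left out except nano-EV library A (adjusted p from 0.0525 to 0.122). In the neural list miR-128-3p, miR-124-3p and miR-9-3p (1.75 ± 0.14) rose, miR-9-5p fell by 2.63 and 1 of 5 did not pass (adjusted p = 0.291). Stromal and endothelial miRNAs had 5 higher, 1 lower and 9 not passing among 15 (adjusted p = 0.153), with miR-126-3p up by 0.61 ± 0.15. In the muscle list, 2 of 4 members were higher (adjusted p = 0.291). These were miR-1-3p (1.73 ± 0.35) and miR-208b-3p, which was listed at 0 in every micro-EV library and at 2.04 to 5.42 CPM in nano-EVs, too near the limit of 3 reads for a fold. The call of miR-208b-3p was lost with DESeq2 (adjusted p = 0.122) and with edgeR without a filter (0.0958). The miR-15/16 family had 3 higher, 1 lower and 7 not passing among 11 (adjusted p = 0.291), and the lower one, miR-16-5p (-0.38 ± 0.12), turned to 0.20 without miR-1246 and miR-1290. Its call was lost in 11 further settings of 23, among them each micro-EV library left out (adjusted p from 0.0525 to 0.137) and nano-EV library A left out (0.0514). Among lymphoid miRNAs, miR-181a-2-3p fell by 1.54 and 4 others did not pass (adjusted p = 0.308). In the miR-23/24/27 clusters miR-24-3p rose by 1.86, 3 members including miR-23a-3p (-0.75 ± 0.14) fell and 5 did not pass (adjusted p = 0.688). Only miR-29a-3p (0.68 ± 0.20) passed among 4 miR-29 miRNAs (adjusted p = 0.688), and not without micro-EV library A (0.0873) or C (0.0917). The medians of the high-numbered, lymphoid and miR-23/24/27 lists changed sign once miR-1246 and miR-1290 were left out. Of the 7 listed miRNAs reported to carry a GGAG sorting motif, 2 were above 0, too few for a list test, and both rose. They were miR-451a and miR-125a-3p (1.26 ± 0.26).

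**Figure D2:**
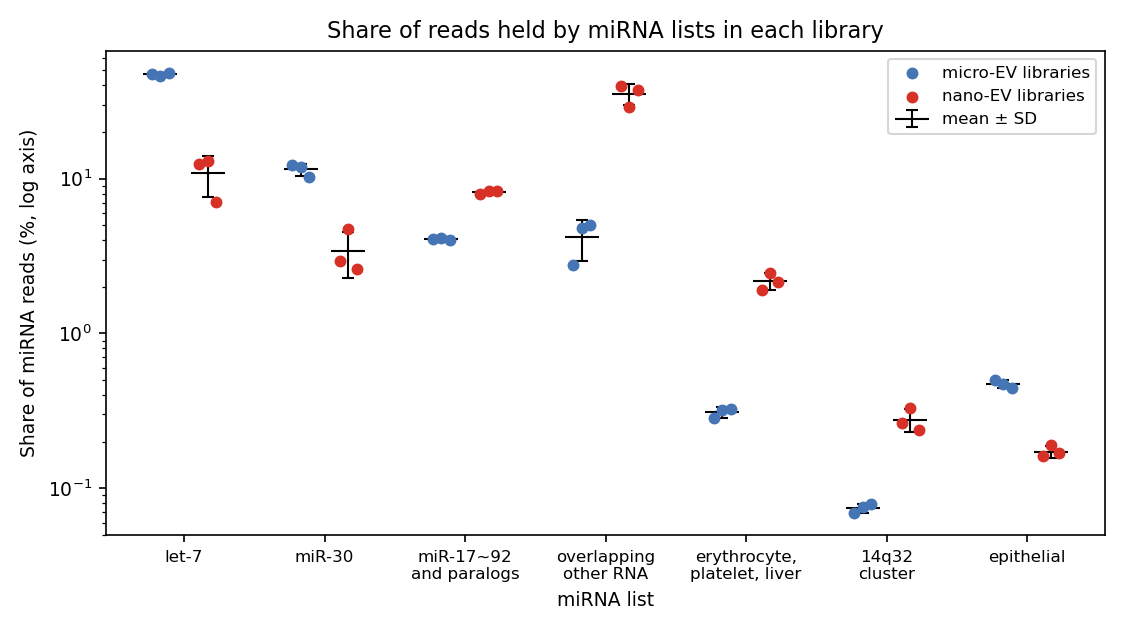
Share of each library's reads held by fixed lists of miRNAs (percent, log axis), with 1 point per library, micro-EV and nano-EV libraries in separate colours, and black bars at the group mean ± SD (n = 3). The let-7 share lies between 46.2% and 47.9% in micro-EV libraries and between 7.11% and 12.9% in nano-EV libraries.

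In all of the 268 called miRNAs the 3 nano-EV libraries lay entirely above or below the 3 micro-EV libraries. Of all tested miRNAs, 316 (54.9%) separated in this way, where chance gives 10%. The called miRNAs held 93.8% of micro-EV and 93.4% of nano-EV reads, and 82.8% of them had a log2 fold change of at least 1 in size. CPM are shares of a library, so a rise of miR-1246 lowers every other miRNA. Without miR-1246 and miR-1290, and with the rest rescaled, 274 miRNAs passed, with 178 (65%) higher and 96 lower, and the median log2 fold change moved up by 0.54. Of the 266 called miRNAs still tested, 82.3% remained called in that setting. Among named miRNAs it ended the calls of miR-20a-5p, miR-23a-3p, miR-30e-5p, miR-142-5p, miR-200b-3p, miR-16-5p, let-7b-5p, miR-548ad-5p and miR-548ae-5p.

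Library composition was compared to ask whether few miRNAs dominate 1 vesicle class more than the other. Let-7a-5p was the most abundant miRNA of the micro-EV libraries and miR-1246 that of the nano-EV libraries. The 10 most abundant miRNAs of each library held 71.4% ± 0.319 of micro-EV and 73.4% ± 3.02 of nano-EV reads (SD, n = 3 per group), a difference of 1.95 percentage points that did not exceed the spread between nano-EV libraries (two-sided exact permutation p = 0.4). The difference was 0.886 points without nano-EV library A and 3.68 points without nano-EV library B. It was -8.37 points without miR-1246 (exact permutation p = 0.1). That setting took out the leader of the nano-EV libraries and kept let-7a-5p, the leader of the micro-EV libraries. A lower nano-EV share was therefore largely built in, and the value does not compare dominance. The smallest p that 3 libraries against 3 can give is 0.1.

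The number of miRNAs detected, with at least 1 read, was 698 ± 19.1 in micro-EV and 688 ± 93.4 in nano-EV libraries (SD, n = 3 per group; two-sided exact permutation p = 0.9). The nano-EV libraries ranged from 600 miRNAs in library C to 786 in library A, in the order of their depth. At 5 or more reads the counts were 406 ± 1.73 and 574 ± 74.0, and after all libraries were thinned to 1050625 reads they were 696 ± 17.8 and 621 ± 60.5. The order of the nano-EV libraries stayed after thinning, at 676 in library A, 630 in B and 556 in C. Depth alone therefore does not account for that order. The count of library A includes miRNAs of the placental chromosome 19 cluster. Of its 66 listed names, 46 had 3 or more reads in nano-EV library A, and all 66 were at 0 in B and C. Their part in the order was not tested. Without nano-EV library C the difference turned from -9.67 to 34.3 miRNAs, and it was -58.7 without nano-EV library A, so no difference in detection was established. MiRNAs of the placental chromosome 19 cluster did not pass the filter for the limma test, with 4933 reads in nano-EV library A, 2 in micro-EV library A and 0 in the other 4 libraries.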

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

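The 3 tests of where this signal came from were chosen after the result was seen. MiRNAs of the chromosome 19 cluster, a primate cluster expressed mainly in placenta, stood out because they had signal in 1 library although the filter on low values kept them out of the comparison of vesicle classes. Alternatives with another filter or none did test some of them. Nano-EV library A held 4933 reads of the cluster, or 913 CPM, while nano-EV libraries B and C and micro-EV libraries B and C held 0 and micro-EV library A held 2. The most abundant were miR-516b-5p at 236 CPM, miR-516a-5p at 93.7 CPM and miR-517a-3p at 85.5 CPM in nano-EV library A. MiR-517a-3p and miR-517b-3p carry identical values, as do 6 further members led by miR-518e-5p, so their reads enter the sum under each name.

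Greater depth of nano-EV library A is argued against, since its CPM would predict 5591 cluster reads in nano-EV libraries B and C together (lower 95% Poisson limit 5445), and these held 0. The limit covers counting error only, and names with identical values enter it more than once, but miR-516b-5p alone would predict 1444 reads there and had 0. Placental RNA or reads carried over into this library are a candidate source. Of the 66 listed cluster miRNAs, names with identical values counted separately, 46 had 3 or more reads there and 15 were at 0, which argues against a single misassigned sequence, and the series' design text names placental vesicles. Transcription of the cluster in the cells behind this library would give the same spread and stays open: the 3 micro-EV libraries held 2 cluster reads in all, but the labels do not say which of them, if any, shares its culture. Leaving out nano-EV library A gave 265 called miRNAs, of which 248 were among the 268 of the full comparison.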

How the results depend on the processing

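Settings added after the data were seen were TMM scaling, edgeR with TMM, thinning for miRNAs and lists (planned for detection), removal of miR-1246 and miR-1290, and the letter block. The count of called miRNAs (268) ranged from 74.3% to 103% of that number over all settings, and no called miRNA was called in the opposite direction in any of them. A sign change without a call occurred for 2 called miRNAs, both without miR-1246 and miR-1290. Leaving out each library gave 81.7% to 103% of the calls, and 3 to 5 lists. With edgeR on recovered reads at a mean of at least 10 CPM the lower count was 91, over 312 tested miRNAs. TMM scaling moved the median log2 fold change by 0.11. Camera with an estimated correlation called 0 lists (1 at an unadjusted p under 0.05) and fry called 15, against 4.

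In the composition comparison the difference was 11.2 points for the single most abundant miRNA, -0.53 for the 50 most abundant and -8.37 without miR-1246. Each of these had an exact permutation p of 0.1, the smallest possible here. Removing miR-1246 alone takes out the leader of the nano-EV libraries only. Leaving out a library gave 0.886 to 3.68. The difference in detected miRNAs was 168 at 5 or more reads, -75.7 at equal depth and from -58.7 to 34.3 when a library was left out. Apart from the thinning, the cause was not tested.

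Without miR-1246 and miR-1290 the medians reversed for high-numbered (0.36), lymphoid (0.30) and miR-23/24/27 (0.27) miRNAs, and miR-16-5p went to 0.20, since the rescaling itself raises every other nano-EV value. The inflammation-responsive median reversed when thinned (-0.056), without micro-EV library A (-0.20) and without nano-EV libraries A (-0.091) or C (-0.43), and the miR-29 median without nano-EV library B (-0.090); the cause was not tested. Over the left-out libraries alone these medians ranged up to 0.16 and 0.42. The miR-17~92 list lost its call at a mean of at least 10 CPM, with TMM scaling, without miR-1246 and miR-1290, and without micro-EV library B or nano-EV library B (adjusted p from 0.0534 to 0.160). The let-7 list gained a call without nano-EV library C (adjusted p = 0.0249). In all, lists gave 201 same calls, 5 losses, 1 gain and 8 reversals over the settings, and named miRNAs 2013, 60, 45 and 1.

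The column letter was also tried as a replicate block, with 260 calls (257 shared with the comparison without it) and 4 lists. Same-letter libraries did not deviate together (correlations -0.04, -0.01 and 0.02). In a balanced design the block leaves mean differences as they are, here 1.95 for composition and -9.67 for detection, so it tests neither. Depth limits miRNAs below about 3 reads, which is 2.71 to 2.86 CPM in micro-EV libraries.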

Other observations

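The tests of the let-7 members and of opposite hairpin arms were chosen after the results were seen. Several abundant miRNAs outside the fixed lists also rose in nano-EVs. The miR-320 family rose in 3 examined members, with log2 fold changes of 1.04 ± 0.14 (SE) for miR-320a-3p, 1.93 ± 0.16 for miR-320b and 2.01 ± 0.16 for miR-320c. MiR-423-5p went from 636 ± 50.8 to 4082 ± 555 CPM (SD, n = 3 per group) and miR-99a-5p from 2830 ± 305 to 6092 ± 1167 CPM. These 5 miRNAs were chosen after their values were seen, and each kept its direction and its call in all 23 alternative settings.

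Arms of 1 hairpin sometimes went opposite ways. Let-7d-5p fell by 2.26 on the log2 scale and let-7d-3p rose by 2.93, let-7b-5p fell by 0.82 (a call lost without miR-1246 and miR-1290) and let-7b-3p rose by 1.96, and miR-9-5p fell by 2.63 and miR-9-3p rose by 1.75. Among 118 hairpins with both arms tested, both arms were called in 32, and 14 of these had opposite calls. Random re-pairing of the called arms gave a median of 16, with a central range from 10 to 22 (permutation p = 0.720), so opposite arms were as frequent as independent calls of the arms give. The count therefore shows neither that arms of a hairpin moved together nor that they were parted, and the hypothesis that vesicle classes part them stays open.

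The rise of all 8 tested erythrocyte, platelet and liver miRNAs in nano-EVs may come from serum vesicles carried over from the culture medium, which contained fetal bovine serum. The test, written before the result was seen, took miR-451a, whose log2 fold change was 1.84 (adjusted p = 2.83e-05), but miR-451a is a member of the list and would rise equally under loading by the cells, so this does not separate the explanations. The most abundant members, miR-486-5p at 15399 CPM, miR-122-5p at 3659 CPM and miR-451a at 1328 CPM in nano-EVs, were present in micro-EVs too, and miR-451a is also on the GGAG-motif list. Deeper sequencing of the nano-EV libraries is argued against, since the list's median was 1.98 at equal depth and 2.01 at full depth. Serum carry-over and selective loading by THP-1 cells both stay open, the latter untested, as no library of cells or unused medium was analysed here.

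The 10 let-7 family members that fell had a median log2 fold change of -2.18. If miR-1246 and miR-1290 had only displaced them from the reads, the fall would end without these 2 miRNAs. The median was then -1.61 ± 0.23 (standard error of the median over the 10 members), and 8 of the 10 were still called. That error treats the members as independent and does not measure the spread between libraries. Over all 17 tested let-7 miRNAs the median went from -1.22 to -0.65 without miR-1246 and miR-1290. The 10 were picked as called lower, and the rescaling moved the median log2 fold change of all miRNAs up by 0.54. A shift of that size could not have ended their fall, so these 2 miRNAs can account for only part of it. Displacement by other miRNAs that rose, such as miR-148a-3p and miR-92a-3p, was not tested. Removal of a smooth trend on hairpin GC content, over the 97.9% of tested miRNAs with a value, left the median at -2.25 ± 0.22 (again an error over the 10 members). The hairpins of the let-7 members named here had a GC of 40.2% to 53.6%. Called higher, called lower and uncalled miRNAs had a median GC of 52.1%, 48.8% and 50.6%. A trend can move miRNAs of such middling GC only little, so the test cannot decide on GC content. A difference in let-7 content between vesicle classes stays a hypothesis, and part of the fall may be displacement. The absolute amount of let-7 per vesicle was not measured.

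The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By limma the real split called 268 miRNAs and was the 1 split with as many, and the highest of the other splits called 0 (4 to 12 at an unadjusted p under 0.05). Every other split mixes the 2 vesicle classes in each group. A difference between classes then adds spread within the groups and lowers the calls, so these splits do not show what chance alone would give. For lists, 2 of the 10 splits called as many as the real one, which called 4, and the highest of the others also called 4.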
